A study of Mus musculus with 46 samples.

How the data were processed

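Whole gonad pairs of mouse embryos at E12.5 were sequenced as poly(A)-selected RNA. Per the labels' protocols, RNA was extracted with the Qiagen RNeasy Plus micro kit and 140 ng of total RNA per sample was made into libraries with NEB poly(A) isolation and NEBNext UltraExpress kits. The genome build was mm10, per the submitters' processing notes. The aligner, the quantifier, the gene annotation and the handling of strand are not given in the sources used here.

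The first deposited table holds estimated counts per gene symbol for each library, which the authors did not normalize as far as the values show. Between 8 and 8.9% of its values per library were not whole numbers, as from a quantifier that shares reads between transcripts, so they were rounded before modelling. The second deposited table holds TPM, which the authors scaled by gene length. Its columns sum to 923510 to 945851 and not to a full TPM total, so some features are not among its rows. Each table also has 1 column with no matching sample in the labels (XX 3bp-del homozygote, replicate 6), which was not used here.

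The 46 libraries were placed in 12 groups of 3 or 5 by sex and genotype as the labels give them. Total estimated counts ran from 29909117 to 46150401 per library, and the 10 most abundant genes took 3.63 to 7.69% of them. No mitochondrial genes are among the rows, so the mitochondrial share could not be computed. The labels give no sequencing batch, and nothing in them says which samples came from the same litter. Pairs of libraries in a group were checked for double deposits, and over 71 pairs the lowest chi-square per degree of freedom was 13.28.

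Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, robust dispersion, TMM normalization) in R 4.3.3, with limma 3.58.1 for list tests. Each comparison was fitted on the libraries of its own groups, with genes kept by filterByExpr over those groups. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are scaled by TMM over all libraries. Log2 CPM values have a prior count of 2. Fold changes are log2 values of the edgeR fit with its default prior, given ± standard error, and CPM values are given ± SD. The standard error was computed as the absolute log2 fold change divided by the square root of F. The differences in effect between the sexes were tested as interaction terms. Of the 33331 gene rows 31323 (94.0%) were matched to 1 chromosome through GENCODE M21 and RefSeq GRCm38.p6, and 17033 genes passed the filter over all groups.

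The comparisons were wild-type XY against wild-type XX, each XX mutant group against wild-type XX, each XY mutant group against wild-type XY, each homozygous XX group against wild-type XY, homozygotes against heterozygotes, homozygous genotypes against each other, and the interactions. The 21 gene lists held 227 genes, of which 224 were in the table, and were written with the design before the data were examined. They cover Sertoli, pregranulosa, steroidogenic, stromal, endothelial, macrophage and erythroid cells, general, male and female germ cells, surface epithelium, mesonephros and adrenal. They also cover Hedgehog targets, the cell cycle, immediate early genes, cholesterol synthesis, basement membrane, genes near Sox9, X inactivation and Y-linked genes. Camera used a preset correlation of 0.01 and, as an alternative, the estimated correlation.

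The Sertoli minus pregranulosa score is the mean log2 CPM of one list minus that of the other. The position of a library is its projection on the line between the wild-type means, over genes called between the wild types with a log2 fold change of at least 1 that are not on the sex chromosomes. Groups were compared by exact 2-sided permutation tests. For the correlation and covariance of fold changes between 2 comparisons with the same wild-type libraries, unchanged groups were simulated.

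Named genes follow a rule: Sox9 always, up to 4 called and up to 2 uncalled genes per list, and the 10 genes that rose most and the 10 that fell most with no overlap between the groups and a mean log2 CPM of at least 1. Genes without a name of their own (predicted genes) were left out. The text gives part of the genes this rule takes, and some are not reported here. Genes from outside it are said to have been chosen after their values were seen.

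Alternatives written with the design were RLE normalization, no expression filter, DESeq2 1.42.0, 1 fit over all 12 groups, replicate numbers as blocks, autosomal genes, and leaving out each library in turn. For the score and the position they were also the median over the list, log2(TPM + 1), an axis from the 3bp-del heterozygotes and an axis from all genes at adjusted p under 0.05. For shared calls they were the sex difference of the 3bp-del heterozygotes and a 2-fold minimum in both comparisons. Gene length here is the relative length of the average transcript of a gene, taken from the ratio of the deposited counts to TPM. Removal of the trend with gene length (16408 of the 17033 genes, 96.33%, have a length), also for the calls of 6 lists, and leaving out the libraries that stood apart were added after the data were seen. So was camera in XY without replicate 3 of XY wild type.

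The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. For wild-type XY against XX (15529 genes), 54 of the former and 75 of the latter were recovered, with 15 false calls. Over all comparisons false calls were 0.752 to 10.6% of the calls by edgeR and 13.1 to 28.9% by DESeq2, which was tested on the 18 comparisons of groups. For XX 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes against XX wild type, 67, 75 and 80 of the genes changed 2-fold and 92, 93 and 86 of those changed 4-fold were recovered. For XX 1bp-ins and 3bp-del heterozygotes these were 66 and 68, and 94 and 86. For XY 1bp-ins heterozygotes and homozygotes, 3bp-del heterozygotes and homozygotes and 3bp-12bp-del homozygotes against XY wild type, 62, 65, 51, 56 and 56 genes changed 2-fold and 90, 88, 76, 84 and 78 changed 4-fold were recovered. For the interactions of 1bp-ins, 3bp-12bp-del and 3bp-del homozygotes these were 52, 51 and 51, and 75, 73 and 76. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.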

Results

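Poly(A)-selected RNA sequencing of whole gonad pairs from mouse embryos at E12.5 was analysed in 46 libraries, 24 XX and 22 XY, from wild type and from 5 genotypes with mutations in Enh13, a remote enhancer of Sox9. The XX groups were wild type (n = 3), 1bp-ins heterozygotes (n = 3), 1bp-ins homozygotes (n = 5), 3bp-del heterozygotes (n = 3), 3bp-del homozygotes (n = 5) and 3bp-12bp-del homozygotes (n = 5). The XY groups had the same sizes except for the 3bp-12bp-del homozygotes (n = 3). The labels do not explain the 3bp-12bp-del genotype. Whether it is an allele with both deletions or a combination of different alleles is not known, and it is called homozygous here as labelled. The libraries held 29909117 to 46150401 estimated counts each, in a table of 33331 gene rows. As far as the labels tell, nothing says that the replicates of a group are separate animals.

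Xist, the RNA that coats the inactive X chromosome, and the Y-linked genes matched the sex label in all 46 libraries. Xist stood at 33.1 to 191 CPM (library-scaled counts) in the XX libraries and at most 0.193 CPM in the XY libraries. The summed Y-linked reads were 149 to 204 CPM in XY and at most 1.87 CPM in XX. In wild-type gonads the Y-linked Ddx3y, Uty, Kdm5d and Eif2s3y were listed at 0 in XX. All 5 measured Y-linked genes were called higher in XY, and Xist was called lower.

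The wild-type XY gonad expressed the Sertoli cell program and its downstream signals, and the wild-type XX gonad expressed the pregranulosa program. Sox9, the transcription factor that starts Sertoli differentiation, was expressed at 136 ± 43 CPM in XY and 9.38 ± 2.3 CPM in XX (log2 fold change 3.83 ± 0.32, adjusted p = 0.000999, edgeR). With it rose Amh, the hormone that removes the female ducts, Dhh, the Hedgehog ligand of Sertoli cells, Fgf9, a growth factor that opposes the ovarian pathway, and Gdnf, a growth factor for germ cells. Foxl2, the transcription factor of pregranulosa cells, the BMP ligand gene Bmp2 and the homeobox gene Msx1 were lower in XY. The Hedgehog targets Gli1, Ptch1 and Hhip were higher in XY, and whether they answered to Dhh was not tested between the wild types.

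Of 20 measured Sertoli genes 17 were higher in XY and 0 lower, and 19 were higher when p values were adjusted over the list alone. Amh rose by 11.15 ± 0.58 log2 units, Dhh by 6.81 ± 0.48, Gdnf by 5.87 ± 0.45 and Fgf9 by 3.20 ± 0.22. Inhbb, an activin subunit, and Dmrt1, a keeper of male identity, were not called (1.12, adjusted p = 0.0727, and 0.76, adjusted p = 0.241). The pregranulosa list had 12 of 15 genes lower and 1 higher in XY, and 13 lower over the list alone. Foxl2 fell by 4.66 ± 0.20 log2 units, Msx1 by 3.37 ± 0.15, the WNT target Sp5 by 3.09 ± 0.25 and Bmp2 by 2.59 ± 0.11. Nkd1 and Axin2, feedback inhibitors of WNT signalling, were not called (-0.55 and -1.43). The correlation-adjusted test of the list against all other genes (camera) called the Sertoli list (adjusted p = 9.04e-46), but adjusted p = 0.085 with an estimated correlation. The pregranulosa list was called under both (adjusted p = 1.58e-33, and adjusted p = 0.0417 with an estimated correlation).

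Of the 4 Hedgehog targets 3 were higher in XY, and all 4 over the list alone. Hhip rose by 3.64 ± 0.33 log2 units, Gli1 by 3.12 ± 0.15 and Ptch1 by 2.29 ± 0.15. This list was called under both correlations (adjusted p = 4.32e-17, and adjusted p = 0.0325 with an estimated correlation). In the steroidogenic list of 12 genes 1 was higher and 2 lower. Hsd17b3, which makes testosterone and at this stage is a Sertoli or fetal Leydig product, rose by 7.49 ± 0.85, and Lhcgr, the luteinizing hormone receptor, fell by 2.18. The Lhcgr call was lost without replicate 1, 2 or 3 of XX wild type or replicate 2 of XY wild type (adjusted p = 0.0579, 0.0912, 0.11 and 0.11).

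Male germ cell genes were among those higher in XY, and no general germ cell marker was called, without a test between these lists. Of 13 general germ cell genes 0 changed by edgeR, with Pou5f1 at -0.37 and Kit at -0.27. In the male germ list 4 of 5 genes were higher in XY. Lefty2 and Lefty1, inhibitors and targets of NODAL, rose by 4.63 ± 0.26 and 3.30 ± 0.35. Nodal itself rose by 1.62, a call lost without any 1 of the wild-type libraries except replicate 3 of XY (adjusted p = 0.0914 to 0.126). The male germ list was called with the preset correlation (adjusted p = 7.14e-07) and not otherwise (adjusted p = 0.19 with an estimated correlation). Of 11 female meiosis genes only Rec8, a meiotic cohesin, was lower in XY (-2.70 ± 0.19), while Stag3 and Smc1b were not called.

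Among the remaining lists, 2 of 8 stromal genes were higher and 1 lower, 1 of 14 endothelial genes was higher and 1 lower, and 0 of 12 macrophage, 0 of 10 erythroid, 0 of 7 mesonephros and 0 of 4 surface epithelium genes changed. Of 10 immediate early genes 4 were higher, with Ier2 up by 0.66 ± 0.10. Of 15 cell cycle genes 3 were higher over all genes and 11 over the list alone, among them Cdk1, Plk1 and Mki67. Of 15 cholesterol synthesis genes 2 were lower, of 11 basement membrane genes 1 was higher (Col18a1, a cord-basement collagen, 1.51 ± 0.12), of 6 adrenal genes 1 was higher (Mc2r, 1.03), and 0 of 7 genes near Sox9 changed. The calls of Cdk1, Plk1, Mki67, Mc2r and the stromal Tcf21 were lost without any 1 of the wild-type libraries except replicate 3 of XY (adjusted p up to 0.132, 0.131, 0.154, 0.0963 and 0.108).

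In all, 1738 of 15730 tested genes differed between the wild-type sexes, 803 higher and 935 lower in XY (adjusted p under 0.05, edgeR), of which 453 and 544 differed by 2-fold or more. By DESeq2 2768 differed, with all 12 groups in 1 fit 5043 and with replicate numbers as blocks 1090. Among the highest were Cbln1, a synapse organizer (5.68 ± 0.44), Ren1, renin (5.50 ± 0.45), Ankrd63 (6.68 ± 0.69), the potassium channel gene Kcns2 (8.35 ± 0.79) and Hsd17b1, an estradiol-forming enzyme (5.05 ± 0.66). Among the lowest were Isx, a homeobox gene (-5.76 ± 0.41), Scrt2, a zinc finger repressor (-5.46 ± 0.30), Stum (-5.18 ± 0.27) and Chrm4, a muscarinic receptor (-4.83 ± 0.11). The count rested on each of the 6 libraries. Without replicates 1, 2 and 3 of XX wild type it was 957, 639 and 723, and without replicates 1, 2 and 3 of XY wild type 831, 852 and 6939. Sox9, Amh, Dhh, Fgf9, Gdnf, Foxl2, Bmp2, Msx1, Sp5, Gli1, Ptch1, Hhip, Lefty1, Lefty2, Rec8 and Col18a1 kept their calls throughout.

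Several libraries carried markers of neighbouring tissue. Replicate 3 of XY wild type had the highest mesonephros list mean (4.66, log2 CPM), with Cdh16, an adhesion protein of kidney tubules, at 82 CPM, Wnt9b at 34.9 and Pax2 at 26.2. Replicate 4 of the XX 3bp-del homozygotes came next at 3.78, with Cdh16 at 41.3 CPM. Replicate 1 of XX wild type had the highest adrenal list mean (3.04) and a mesonephros mean of 2.97, with Dbh and Th, the enzymes of catecholamine synthesis, at 80 and 36.5 CPM. Replicate 1 of the XY 3bp-del heterozygotes followed with an adrenal mean of 2.43 and Dbh at 31.3 CPM.

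XX gonads of each of the 3 genotypes labelled homozygous expressed Sox9 and had most of the Sertoli program. Their mean Sox9 lay above that of wild-type XY gonads, with no call by edgeR on each comparison's own groups. It lay below the mean of XY homozygotes of the same mutation, without a test of that difference. Sox9 rose from 9.38 ± 2.3 CPM to 171 ± 31 CPM in 1bp-ins homozygotes (4.18 ± 0.22 log2 units, adjusted p = 0.000265), 181 ± 23 CPM in 3bp-del homozygotes (4.23 ± 0.18, adjusted p = 3.04e-06) and 215 ± 41 CPM in 3bp-12bp-del homozygotes (4.51 ± 0.24, adjusted p = 7.53e-05, all edgeR). Fgf9, Mmd2, a Golgi protein of early Sertoli cells, Inhbb and Cyp26b1, which degrades retinoic acid, rose as well. Foxl2, Fst, an activin antagonist, and Irx3 fell, with means that stayed above those of wild-type XY. The male germ cell signals Lefty1 and Lefty2 rose, while few Hedgehog targets did.

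**Figure D1:**
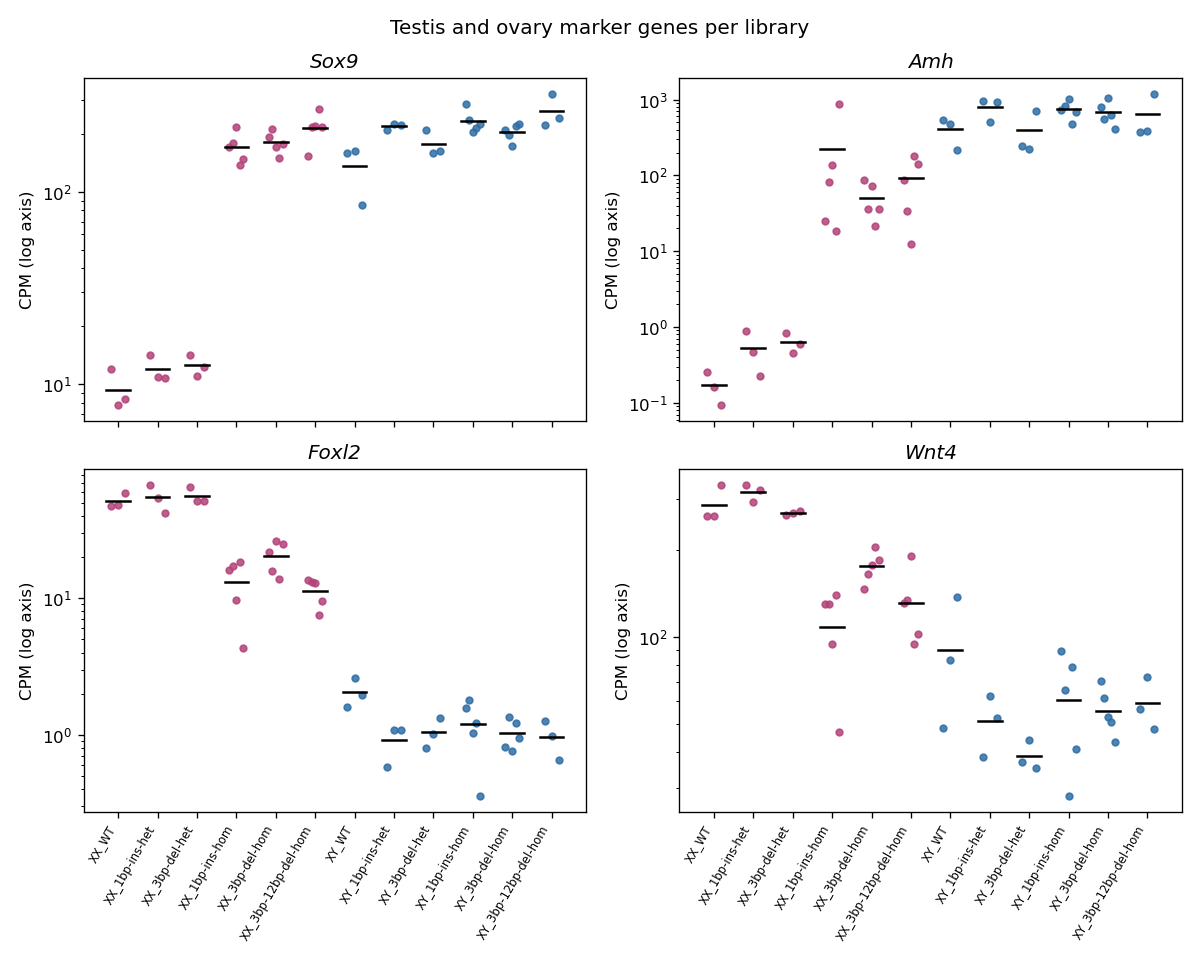
CPM of Sox9, Amh, Foxl2 and Wnt4 in each of the 46 libraries, on a log axis. Bars are group means, and libraries are ordered by sex and genotype.

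In 1bp-ins homozygotes 18 of 20 Sertoli genes rose and 0 fell. Fgf9 rose by 3.16 ± 0.20 log2 units, Mmd2 by 5.38 ± 0.54 and Inhbb by 1.08 ± 0.13, while Cldn11, a tight junction gene, and Vnn1 were not called (0.35 and 1.22). Of 15 pregranulosa genes 10 fell and 0 rose. Fst fell by 2.73 ± 0.54, Irx3 by 1.74 ± 0.34, Axin2 by 1.11 ± 0.13 and the WNT effector Lef1 by 0.91 ± 0.16, with Nkd1 and Runx1 not called (-0.53 and -0.61). Hsd17b3 rose by 6.78 ± 1.42, Lefty2 by 4.25 ± 0.66 and Lefty1 by 3.37 ± 0.69. Tcf21, a stromal transcription factor, rose by 0.91 ± 0.12 and Efnb2, an arterial ephrin, by 0.57 ± 0.07, each the 1 gene of its list that rose, while 2 of 8 stromal and 5 of 14 endothelial genes fell (2 endothelial genes with the trend of fold change with gene length removed). Of the 4 Hedgehog targets only Gli1 was called (1.84, adjusted p = 0.0448), and its call was lost without replicate 2 or 3 of this group (adjusted p = 0.0614 and 0.0797) or without replicate 1, 2 or 3 of XX wild type (adjusted p = 0.11, 0.118 and 0.142). Replicate 5 of this group had a mean log2 CPM of 6.03 over the Hedgehog targets, against 2.79 to 3.67 in its fellow libraries.

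In 3bp-del homozygotes 18 of 20 Sertoli genes rose and 0 fell, with Fgf9 up by 3.18 ± 0.12 log2 units, Mmd2 by 4.66 ± 0.27 and Gdnf by 3.80 ± 0.27. Of 15 pregranulosa genes 9 fell and 1 rose. Fst fell by 2.21 ± 0.16, Foxl2 by 1.35 ± 0.21, Wnt4, the ligand of the ovarian pathway, by 0.73 ± 0.12 and Lef1 by 0.52 ± 0.08. Rspo1, its R-spondin partner, was not called (-0.42, adjusted p = 0.0515). Star, which brings cholesterol into mitochondria, rose by 0.82 ± 0.09 and Hsd17b3 by 5.73 ± 0.72, while Cyp11a1, the first steroidogenic enzyme, was not called (-0.31). Gli1 rose by 1.04 ± 0.22 and Ptch1 was not called (-0.04). Hhip fell by 1.35 ± 0.34 (adjusted p = 0.00803), with adjusted p = 0.454 when all 12 groups were in 1 fit and 0.000929 to 0.454 over all alternatives. Lefty2 rose by 3.79 ± 0.38, Lefty1 by 2.68 ± 0.32 and Utf1, a pluripotency factor of germ cells, by 0.91 ± 0.20. Of the endothelial list 2 of 14 rose and 8 fell, among them Tek, Kdr and Tie1, and 5 fell with the length trend removed.

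In 3bp-12bp-del homozygotes 17 of 20 Sertoli genes rose and 0 fell, with Fgf9 up by 3.27 ± 0.14 log2 units, Cyp26b1 by 2.84 ± 0.19 and Inhbb by 1.30 ± 0.08. Sox10 and Cldn11 were not called (3.27, adjusted p = 0.0737, and 0.04). Of 15 pregranulosa genes 13 fell and 1 rose. Foxl2 fell by 2.17 ± 0.18, Irx3 by 1.90 ± 0.26 and Axin2 by 0.99 ± 0.13, and Lgr5, a receptor for R-spondins, rose by 1.09 ± 0.09. Star rose by 1.02 ± 0.11, Scarb1, a lipoprotein receptor, by 0.42 ± 0.08 and Hsd17b3 by 6.25 ± 1.00. Lefty2 rose by 3.80 ± 0.33, Lefty1 by 2.56 ± 0.36 and Nodal by 1.18 ± 0.25. Of 14 endothelial genes 1 rose and 0 fell by edgeR. Ptch1 rose by 0.96, a call lost without replicate 4 or 5 of this group or any XX wild-type library (adjusted p = 0.0628 to 0.0965). Hhip fell by 1.25, a call lost without replicate 2 or 4 of this group or any XX wild-type library (adjusted p = 0.0583 to 0.0764).

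Some genes of other lists changed in all 3 homozygous XX groups, and others in only part of them. Of 15 cell cycle genes 12, 11 and 10 rose in 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes, with Pcna, the sliding clamp of replication, up by 0.67 ± 0.09, 0.63 ± 0.08 and 0.50 ± 0.07 log2 units. Of the 11 basement membrane genes 6, 9 and 3 fell and 0, 1 and 1 rose. That list was called down in 1bp-ins and 3bp-del homozygotes and not in 3bp-12bp-del (adjusted p = 0.00224, 1.92e-05 and 0.388, and adjusted p = 0.585, 0.596 and 0.898 with an estimated correlation). It was also called down in 1bp-ins and 3bp-del heterozygotes, where Sox9 was not called (adjusted p = 0.00623 and 0.00203, and adjusted p = 0.857 and 0.941 with an estimated correlation). Fold change fell with gene length in all 5 XX groups (Spearman's rho across genes -0.391, -0.480 and -0.218 in the homozygotes and -0.410 and -0.449 in the heterozygotes). These comparisons share the XX wild-type libraries. The trend was not limited to XX: against XY wild type rho was -0.516 and -0.310 in XY 1bp-ins and 3bp-del homozygotes. In the other XY groups it was -0.0438 to 0.0723. With that trend removed 5, 5 and 3 basement membrane genes fell in the XX homozygotes, and 0 and 1 in the XX heterozygotes. Of 15 cholesterol synthesis genes 6, 1 and 1 rose and 1, 6 and 0 fell. Agrn, agrin, fell by 0.75 ± 0.12, 0.95 ± 0.10 and 0.46 ± 0.08. Ier2 and Jun, immediate early genes, rose in all 3 groups. Ret, the GDNF receptor and a gene of the mesonephros list, fell by 1.77 ± 0.34, 1.92 ± 0.20 and 2.14 ± 0.26. Of that list 2 of 7, 1 of 8 and 3 of 8 genes fell, with medians of -1.17, 0.10 and -1.29, and in replicate 1 of XX wild type, which carried mesonephros markers, Ret was 18.0 CPM, the highest of that group. Cog1, a Golgi gene near Sox9, rose by 0.29 ± 0.05, 0.30 ± 0.07 and 0.25 ± 0.07, and the other 6 measured genes near Sox9 were not called. The Cog1 call in 3bp-12bp-del was lost without any 1 of its libraries except replicate 3 of the homozygotes (adjusted p = 0.0508 to 0.0953). Of 12 macrophage genes 2, 4 and 5 fell, while the general germ cell list changed only by Utf1 and the female meiosis list had 0 calls by edgeR in all 3 groups.

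Camera called the Sertoli, pregranulosa, male germ and cell cycle lists in all 3 homozygous XX groups with the preset correlation and in none with an estimated correlation. For the Sertoli list of 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes the values were adjusted p = 6.16e-25, 4.16e-32 and 1.17e-47, against adjusted p = 0.352, 0.156 and 0.0611 with an estimated correlation. For the pregranulosa list they were 8.52e-07, 1.92e-05 and 1.59e-11, against adjusted p = 0.585, 0.676 and 0.293 with an estimated correlation. For the male germ list they were 0.0248, 0.0139 and 0.000377, against adjusted p = 0.585, 0.676 and 0.293 with an estimated correlation. The cell cycle list had 6.6e-06, 0.000709 and 0.000101, against adjusted p = 0.585, 0.82 and 0.558 with an estimated correlation.

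Among the genes outside the lists that rose most in each homozygous XX group was BC006965, a noncoding transcript from the minus strand of chromosome 11 (112663927 to 112781976, mm10). Its 5' end lies 248 bp from the start of Sox9 (112782224 to 112787760, plus strand). It rose by 6.20 ± 0.73, 6.03 ± 0.56 and 6.19 ± 0.55 log2 units in 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes, from 0.0483 CPM to 3.65, 3.31 and 3.63 CPM. How strand was handled is not stated, so reads of the 2 divergent genes cannot be separated with certainty. Cbln4, Mt3, a metallothionein, and Fzd9, a WNT receptor, also rose in all 3 groups. Among the genes that fell most were Stum (-2.45, -2.05 and -2.15), Pld5 (-2.28, -2.17 and -2.22), Efcab7 and Insyn2b in all 3 groups, and Slc7a11, a cystine transporter, in the 1bp-ins and 3bp-del homozygotes (-2.58 and -2.40). In 3bp-12bp-del homozygotes the pseudogene Rpl7a-ps11 rose by 5.41 ± 0.91, which is uncertain because it resembles a ribosomal protein gene.

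The totals were 5187 of 16040 genes in 1bp-ins homozygotes (2759 higher, 2428 lower), 7175 of 16031 in 3bp-del homozygotes (3470 and 3705) and 4088 of 15957 in 3bp-12bp-del homozygotes (2331 and 1757). Changes of 2-fold or more made up 353 and 377, 346 and 504, and 417 and 355 of these. With the trend of fold change with gene length removed the counts were 3439 (2071 and 1368), 5616 (3221 and 2395) and 4018 (2370 and 1648), of which 2778, 4384 and 3509 were among the totals above. With replicate numbers as blocks they were 4859, 8279 and 1217. Without replicates 2 and 3 of XX wild type the count for 1bp-ins homozygotes was 3026 and 3247, and for 3bp-12bp-del homozygotes 2276 and 2713. Sox9, Fgf9, Lefty1, Lefty2, Hsd17b3, BC006965, Cbln4, Mt3, Fzd9, Stum and Pld5 kept their calls in every setting tested.

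**Figure D2:**
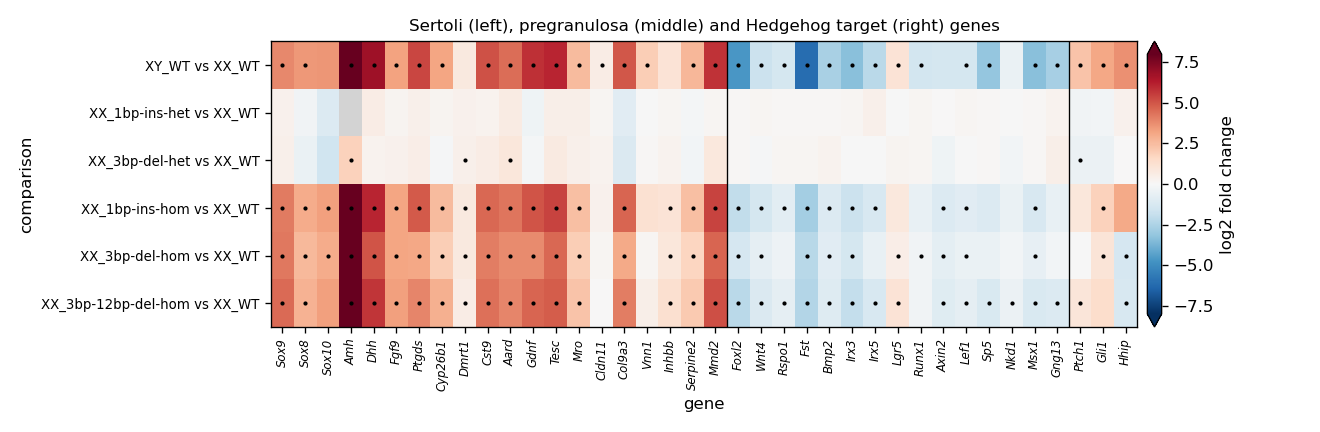
Log2 fold changes of Sertoli genes, pregranulosa genes and 3 Hedgehog targets in 6 comparisons with wild-type XX. Dots mark called genes, grey marks genes not tested, and colours are limited to 8 log2 units in each direction.

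Heterozygous XX gonads had Sox9 close to wild-type XX, and no pregranulosa gene was called in either genotype. Sox9 was 11.95 ± 1.9 CPM in 1bp-ins heterozygotes (0.34 ± 0.19 log2 units, adjusted p = 0.698) and 12.54 ± 1.6 CPM in 3bp-del heterozygotes (0.40 ± 0.18, adjusted p = 0.201), and was not called in either. Without replicate 1 of XX wild type Sox9 was called in 3bp-del heterozygotes (0.62, adjusted p = 0.0395, range over all alternatives 0.0395 to 0.471). In 1bp-ins heterozygotes 0 of 15694 genes changed by edgeR, with 1251 at unadjusted p under 0.05 and 86 by DESeq2. The count was 1 without replicate 1 or 3 of this group and 1 without replicate 1 or 3 of XX wild type. In 3bp-del heterozygotes 3 of 20 Sertoli genes rose, Aard (0.92 ± 0.14), Amh (1.83 ± 0.47, at 0.63 against 0.17 CPM) and Dmrt1 (0.38 ± 0.10), and 0 of 15 pregranulosa genes changed, with Wnt4 at -0.11 and Fst at 0.16. The Amh and Dmrt1 calls were lost without any 1 of the 6 libraries (adjusted p = 0.052 to 0.162 and 0.0565 to 0.176). The Aard call was lost without replicate 2 of XX wild type (adjusted p = 0.0691, range over all alternatives 1.18e-06 to 0.142).

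Several noncoding RNAs were among the genes that fell in 3bp-del heterozygotes. Kcnq1ot1, the RNA that silences an imprinted cluster, fell by 2.05 ± 0.15 log2 units, Snhg17, a small nucleolar RNA host, by 1.74 ± 0.18, Hmcn1, a very long matrix gene, by 1.57 ± 0.10 and Efcab7 by 2.17 ± 0.28. Malat1, an RNA of nuclear speckles, fell by 2.32 ± 0.41, and its call was lost without replicate 1 of XX wild type or without any 1 of the 3 heterozygous libraries (adjusted p = 0.074 to 0.124). Etnk2, an ethanolamine kinase, rose by 1.09 ± 0.11. In total 1721 of 15742 genes changed, 753 higher and 968 lower (edgeR), of which 13 and 84 changed by 2-fold or more. By DESeq2 2656 changed, with all 12 groups in 1 fit 723, and with replicate numbers as blocks 507 (119 higher, 388 lower). With the length trend removed 441 changed, and Malat1 was not called (-2.27, adjusted p = 0.0576). Without replicates 1, 2 and 3 of XX wild type the count was 1055, 165 and 1097, and without replicates 1 and 2 of the heterozygotes 687 and 1083. Camera called the Sertoli list up in 1bp-ins and 3bp-del heterozygotes (adjusted p = 0.00623 and 0.028, and adjusted p = 0.857 and 0.941 with an estimated correlation). In 1bp-ins heterozygotes it also called the erythroid list up (adjusted p = 0.00623, and adjusted p = 0.857 with an estimated correlation). The erythroid median was 0.49 log2 units there, against 0.21 for the Sertoli list.

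Against heterozygotes of the same mutation Sertoli genes were higher and pregranulosa genes lower in homozygous XX gonads, with no wild-type library involved. In 1bp-ins, Sox9 rose by 3.83 ± 0.18 log2 units, Fgf9 by 2.92 ± 0.28, Mmd2 by 5.21 ± 0.56 and Inhbb by 0.90 ± 0.12, with 16 of 20 Sertoli genes higher and 11 of 15 pregranulosa genes lower, among them Axin2 (-1.13 ± 0.12), Lef1 (-1.09 ± 0.16) and Irx3 (-1.91 ± 0.33). In 3bp-del, Sox9 rose by 3.85 ± 0.13, Fgf9 by 2.82 ± 0.12, Sox10, a relative of Sox9, by 4.65 ± 0.21 and Gdnf by 3.98 ± 0.28, with 18 of 20 Sertoli genes higher and 11 of 15 pregranulosa genes lower, among them Fst (-2.35 ± 0.13) and Bmp2 (-1.16 ± 0.13). Nr4a3, a nuclear receptor, rose by 3.78 ± 0.48 and 3.76 ± 0.27, and BC006965 by 5.66 ± 0.87 and 5.82 ± 0.56. In 1bp-ins 2751 of 15933 genes changed and in 3bp-del 4326 of 15979. Without replicates 2 and 3 of the 1bp-ins heterozygotes the count was 645 and 693, without replicates 2 and 3 of the 1bp-ins homozygotes 1461 and 1255, and without replicates 1 and 3 of the 3bp-del heterozygotes 2787 and 2653. The Sertoli list had adjusted p = 7.86e-35 in 1bp-ins and 1.36e-59 in 3bp-del, and adjusted p = 0.193 and 0.0495 with an estimated correlation. The pregranulosa list had adjusted p = 1.05e-12 and 2.89e-12, and adjusted p = 0.419 and 0.0597 with an estimated correlation.

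Compared with wild-type XY gonads, homozygous XX gonads had no called change in Sox9 by edgeR on each comparison's own groups. Several pregranulosa genes and Hedgehog targets were called in 3bp-del and 3bp-12bp-del. Fewer were called in 1bp-ins, where camera called both lists with the preset correlation only. Between 1bp-ins and 3bp-del homozygotes 0 of 15 pregranulosa genes and 0 of 4 Hedgehog targets were called. Sox9 was not called in 1bp-ins (0.33 ± 0.23 log2 units), 3bp-del (0.42 ± 0.21) or 3bp-12bp-del homozygotes (0.66 ± 0.23, adjusted p = 0.151). In the last group Sox9 was called by DESeq2 (adjusted p = 0.0399) and with all 12 groups in 1 fit (adjusted p = 0.0102), with 0.0102 to 0.465 over all alternatives. In 3bp-del homozygotes 11 of 15 pregranulosa genes were higher than in XY, with Foxl2 up by 3.32 ± 0.28, Msx1 by 2.70 ± 0.15, Sp5 by 2.59 ± 0.22 and Bmp2 by 1.71 ± 0.16. The Hedgehog targets Hhip, Ptch1 and Gli1 were lower by 4.99 ± 0.39, 2.32 ± 0.14 and 2.07 ± 0.18. Of 20 Sertoli genes 11 were lower, such as Vnn1 (-1.83 ± 0.22), Gdnf (-2.06 ± 0.30), Ptgds, a prostaglandin synthase (-2.25 ± 0.35), and Col9a3 (-1.92 ± 0.30). Rec8 was higher by 2.53 ± 0.17, Dnd1, an RNA-binding protein of germ cells, by 1.01 ± 0.18, and Col18a1 was lower by 1.00 ± 0.11. In its list 6 of 11 basement membrane genes were lower and 0 higher, and 5 were lower with the length trend removed. The pregranulosa and Hedgehog lists were called under both correlations (adjusted p = 1.27e-22 and 1.44e-17, and adjusted p = 0.0212 and 0.00581 with an estimated correlation).

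In 3bp-12bp-del homozygotes against wild-type XY, 8 of 15 pregranulosa genes were higher, with Foxl2 up by 2.46 ± 0.26 log2 units, Msx1 by 2.13 ± 0.27 and Sp5 by 1.81 ± 0.24, and 3 of 4 Hedgehog targets were lower, with Hhip at -4.94 ± 0.41. Of 20 Sertoli genes 2 were lower. The Vnn1 call (-1.52) was lost without replicate 1 or 2 of either group (adjusted p = 0.0539 to 0.0957), and the Cldn11 call (-0.61) without replicate 1, 2, 3 or 5 of the homozygotes or 1 or 2 of XY wild type (adjusted p = 0.0741 to 0.155). Scrt2, Chrm4 and Phlda2, an imprinted growth gene, were higher by 4.67 ± 0.60, 3.76 ± 0.45 and 3.24 ± 0.35. Inhba, another activin subunit, and Sostdc1, a BMP antagonist, were lower by 3.18 ± 0.50 and 3.24 ± 0.52. In 1bp-ins homozygotes 1 of 15 pregranulosa genes was higher over all genes and 7 over the list alone, and the 1 was Gng13 (2.07, a call lost without any 1 of replicates 1 to 4 or of the XY wild-type libraries, adjusted p = 0.0893 to 0.22). Of the Hedgehog targets 0 of 4 were called in 1bp-ins homozygotes and 3 were lower over the list alone. The pregranulosa list of 3bp-12bp-del and 1bp-ins homozygotes had adjusted p = 8.43e-16 and 4.02e-11 and the Hedgehog list 1.88e-09 and 0.0012, against adjusted p = 0.0686 and 0.334 for either list with an estimated correlation.

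The totals against wild-type XY were 20 of 15916 genes in 1bp-ins homozygotes (8 higher, 12 lower, 10 of them autosomal), 2797 of 15899 in 3bp-del homozygotes (1367 and 1430) and 886 of 15815 in 3bp-12bp-del homozygotes (536 and 350). By DESeq2 these were 622, 3875 and 1769, with all 12 groups in 1 fit 1960, 4889 and 2290, and with replicate numbers as blocks 1, 596 and 267. For 1bp-ins homozygotes the count was 33 with no filter, 40 with the length trend removed and 3 with autosomal genes only. In 1bp-ins homozygotes, apart from Xist and the Y-linked genes, Epx, eosinophil peroxidase (2.15), and the X-linked Eif2s3x (0.61) were higher, and Wnk4, a kinase of ion transport (-0.70), was lower. The calls of Epx, Eif2s3x and Wnk4 were lost without replicate 1 or 2 of the homozygotes and without replicate 2 of XY wild type (adjusted p up to 0.119, 0.118 and 0.092). Those of Eif2s3x and Wnk4 were also lost without replicate 1 of XY wild type (0.115 and 0.0569), and that of Eif2s3x without replicate 3 or 4 of the homozygotes (0.0561 and 0.0537). The 20 rested on replicate 5, without which 575 genes changed. It was 7, 6, 10 and 13 without replicates 1 to 4, and 8, 6 and 12 without replicates 1, 2 and 3 of XY wild type. For 3bp-del homozygotes the count without replicates 1, 2, 3 and 5 was 1658, 1747, 1546 and 1447, and without replicate 1 of XY wild type 1114. For 3bp-12bp-del homozygotes it was 492, 353 and 557 without replicates 1, 2 and 5, and 323, 442 and 2474 without replicates 1, 2 and 3 of XY wild type.

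Between the homozygous XX genotypes Sox9 was not called (-0.08 ± 0.12 log2 units for 1bp-ins against 3bp-del, 0.25 ± 0.13 for 3bp-12bp-del against 3bp-del). Without replicate 1 of 3bp-12bp-del it was called in the latter (0.36, adjusted p = 0.0233, range over all alternatives 0.0233 to 0.617). Between 1bp-ins and 3bp-del 21 of 15653 genes changed (8 higher, 13 lower), with Lpcat2, a phospholipid enzyme, up by 1.18 ± 0.13 and the ribosomal protein gene Rpl27 down by 0.53 ± 0.06 (call lost without replicates 1 and 5 of 3bp-del, adjusted p = 0.0601 and 0.0502), and several pseudogenes of ribosomal proteins among the others that are uncertain. This count was 11, 10 and 7 without replicates 1, 3 and 4 of 1bp-ins, and 3, 13, 8, 32 and 5 without replicates 1 to 5 of 3bp-del. Between 3bp-12bp-del and 3bp-del 4360 of 15605 genes changed (2327 higher, 2033 lower), of which 59 and 37 by 2-fold or more. The former had more Cyp26b1 (0.83 ± 0.18), Ptch1 (0.97 ± 0.20), Pdgfra (0.45 ± 0.05), Kdr (0.50 ± 0.07) and Hmcn1 (1.56 ± 0.21), and less Foxl2 (-0.85 ± 0.21), Sp5 (-0.76 ± 0.19) and Derpc (-3.07 ± 0.35). The endothelial list had 6 of 14 genes higher and 2 lower, against 3 and 1 with the length trend removed. Of 11 basement membrane genes 9 were higher, such as Lamc1 (0.61 ± 0.06), Lamb1 (0.51 ± 0.06) and Hspg2 (0.70 ± 0.11). That list had adjusted p = 3.52e-09, and adjusted p = 0.156 with an estimated correlation. It holds long genes (median length percentile 87.3), and in this comparison the fold change rose with gene length across genes (Spearman's rho 0.502, genes are not independent replicates). With the length trend removed 2494 genes changed, 1752 of them among the 4360, and 4 of the 11 basement membrane genes were higher, with the list median going from 0.51 to 0.33. Lamc1, Lamb1, Hspg2 and Hmcn1 then stayed called (0.45, 0.28, 0.50 and 1.37).

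In XY gonads the same mutations gave 0 to 2 called genes by edgeR on each comparison's own groups, and more by other fits. Sox9 was 219 ± 9.1, 233 ± 31, 177 ± 29, 205 ± 21 and 262 ± 53 CPM in 1bp-ins heterozygotes, 1bp-ins homozygotes, 3bp-del heterozygotes, 3bp-del homozygotes and 3bp-12bp-del homozygotes, against 136 ± 43 CPM in wild type, and was not called in any (0.68, 0.78, 0.38, 0.59 and 0.95 log2 units, smallest adjusted p = 0.341). By DESeq2 and with all 12 groups in 1 fit Sox9 was called higher in 1bp-ins homozygotes (adjusted p = 0.0263 and 0.0211, range over all alternatives 0.0211 to 0.674) and in 3bp-12bp-del homozygotes (0.0333 and 0.0108, range 0.0108 to 0.999). By edgeR 0 of 15336, 0 of 15693, 0 of 15261 and 0 of 15812 genes changed in the first 4 groups. At unadjusted p under 0.05 these had 943, 2232, 740 and 1722 genes, by DESeq2 27, 124, 25 and 179, and with all 12 groups in 1 fit 1, 802, 188 and 652. In 3bp-12bp-del homozygotes 2 of 15390 genes rose, Ncan, a matrix proteoglycan (2.46 ± 0.19), and Tmem254 (1.37 ± 0.08), with 1052 at unadjusted p under 0.05, 135 by DESeq2 and 210 with all 12 groups in 1 fit. Both calls were lost without any 1 library except replicate 3 of XY wild type (adjusted p = 0.167 to 0.361 and 0.0841 to 0.174). Without replicate 3 of XY wild type the counts were 5 in 1bp-ins heterozygotes, 3 in 3bp-del heterozygotes and 56 in 3bp-12bp-del homozygotes, which had 0 without any other library. Without replicate 1 of the 3bp-del homozygotes that group had 3.

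Amh was 412 ± 171 CPM in wild-type XY gonads and 395 to 797 CPM in the XY mutant groups, and Dhh was 148 ± 63.9 CPM and 193 to 245 CPM, and these values were chosen after they were seen. With the preset correlation camera called 11, 6, 9, 9 and 5 lists in the 5 comparisons, among them the Sertoli list up and the mesonephros list down in each. The pregranulosa list was called down in the first 4 (adjusted p = 3.45e-05, 0.045, 9.33e-05 and 0.0164) and not in 3bp-12bp-del homozygotes (0.0623), and in none with an estimated correlation (adjusted p = 0.401, 0.706, 0.418, 0.527 and 0.674). These share the 3 XY wild-type libraries and are not independent, and replicate 3 of XY wild type had the lowest score of the XY libraries (1.63, next 2.89). The Sertoli values were adjusted p = 1.54e-17, 1.82e-10, 5.08e-05, 1.47e-10 and 1.16e-07, against adjusted p = 0.401, 0.706, 0.418, 0.527 and 0.674 with an estimated correlation. The mesonephros medians were -2.17, -2.12, -1.85, -2.19 and -2.31 log2 units, in the direction of the mesonephros markers Cdh16, Wnt9b and Pax2 in replicate 3 of XY wild type. Those calls had adjusted p = 4.56e-05, 0.00116, 9.33e-05, 0.00033 and 0.00705, against adjusted p = 0.401, 0.706, 0.418, 0.527 and 0.674 with an estimated correlation. Camera also called the erythroid list up in 1bp-ins heterozygotes and homozygotes (adjusted p = 1.54e-07 and 2.98e-17, and adjusted p = 0.401 and 0.368 with an estimated correlation). In the homozygotes 9 of 10 erythroid genes were higher over the list alone. It called the macrophage list down in all groups but the 1bp-ins homozygotes (adjusted p = 3.68e-09, 0.000178, 0.00033 and 0.000246, and adjusted p = 0.401, 0.418, 0.527 and 0.674 with an estimated correlation). Without replicate 3 of XY wild type the Sertoli values were adjusted p = 1.59e-10, 0.000123, 0.726, 0.000702 and 0.0885, with medians of 0.34, 0.22, 0.08, 0.11 and 0.17, and the mesonephros list was called in the 1bp-ins and 3bp-del heterozygotes only (adjusted p = 0.0354 and 0.0185). The pregranulosa list was then called in the same 2 groups (adjusted p = 0.0147 and 0.00177) and the macrophage list in the 1bp-ins heterozygotes only (adjusted p = 0.0021). The erythroid list stayed called in both 1bp-ins groups (adjusted p = 0.00771 and 2.6e-24) and was called down in 3bp-12bp-del homozygotes (adjusted p = 0.00692). With an estimated correlation these lists were then not called in any of the 5.

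The genes in which the effect of a homozygous mutation differed between the sexes included Sertoli genes. The change in XX exceeded the change in XY for Sox9 by 3.40 ± 0.30 log2 units in 1bp-ins, 3.66 ± 0.28 in 3bp-del and 3.57 ± 0.36 in 3bp-12bp-del homozygotes. For Fgf9 the excess was 2.93 ± 0.26, 3.26 ± 0.25 and 3.06 ± 0.23, for Mmd2 5.06 ± 0.60, 4.18 ± 0.46 and 4.68 ± 0.54, and for Lefty2 4.17 ± 0.70, 3.69 ± 0.39 and 4.02 ± 0.49. Of 20 Sertoli genes 11, 13 and 10 were called, all in this direction, and the list was called under both correlations (adjusted p = 0.0165, 0.0218 and 0.0247 with an estimated correlation). In total 171 of 16422, 631 of 16483 and 97 of 16259 genes were called, and 512, 1954 and 437 with all 12 groups in 1 fit. Without replicate 3 of XY wild type these counts were 1590, 3834 and 2959. Without replicates 2 and 3 of XX wild type and 1 and 2 of XY wild type the 1bp-ins count was 71, 82, 82 and 90, and the 3bp-del count 265, 275, 420 and 234. The 3bp-del count was also 378, 386 and 396 without replicates 1, 3 and 5 of its XX homozygotes, and 410 and 389 without replicates 2 and 3 of its XY homozygotes. The 3bp-12bp-del count was 62, 13 and 10 without replicates 1 to 3 of XX wild type and 11 and 11 without replicates 1 and 2 of XY wild type. It was 208, 62 and 31 without replicates 3 to 5 of its XX homozygotes, and 16, 27 and 37 without replicates 1 to 3 of its XY homozygotes.

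The Sertoli minus pregranulosa score, a difference of mean log2 CPM over the 2 lists, placed the means of the homozygous XX groups between those of the wild types. The score was -3.75 ± 0.53 in XX wild type and 2.73 ± 0.97 in XY wild type. In XX 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes it was 0.963 ± 1.30, 0.0321 ± 0.297 and 0.739 ± 0.789. Replicate 5 of the 1bp-ins homozygotes, at 2.99, lay above the XY wild-type mean. The differences of 4.72, 3.79 and 4.49 had exact 2-sided permutation p = 0.0179, the smallest possible with n = 3 and n = 5 libraries (adjusted p = 0.0298). Heterozygotes differed by 0.12 and 0.25 (exact p = 0.8 and 0.4, smallest possible 0.1). In XY the differences were 1.19, 0.90, 0.83, 0.76 and 0.79 for 1bp-ins heterozygotes and homozygotes, 3bp-del heterozygotes and homozygotes and 3bp-12bp-del homozygotes, with adjusted p 0.208 to 0.4. Without replicate 3 of XY wild type they were 0.64, 0.35, 0.28, 0.21 and 0.24. Shares of the wild-type switch, in log2 CPM, were taken over the genes called between the wild types with a 2-fold difference, 16 of 20 Sertoli and 13 of 15 pregranulosa genes. The median Sertoli gene reached 84.1%, 75.4% and 80.5% in the 3 homozygous XX groups (lowest 35.0%, 8.38% and 21.7%, highest 110%, 112% and 118%). The median pregranulosa gene reached 51.8%, 29.4% and 47.6% (lowest 21.2%, 7.85% and 21.5%, highest 83.5%, 47.0% and 98.1%). The highest in the last 2 groups was Lgr5, which is higher in wild-type XY (1.11) and rose, so its share is no loss of ovarian expression.

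**Figure D3:**
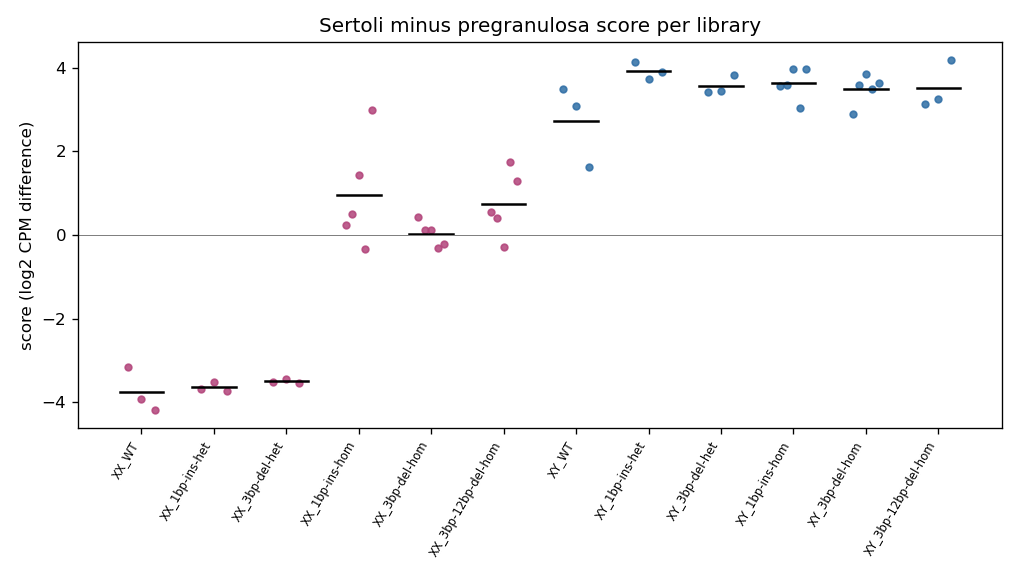
Sertoli minus pregranulosa score of each library, with group means as bars.

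On the line from the mean of wild-type XX (0) to that of wild-type XY (1), taken over the 932 genes of the wild-type sex difference (420 higher in XY, 512 higher in XX), heterozygous XX libraries stood at 0.0150 ± 0.0231 (1bp-ins) and 0.0238 ± 0.0192 (3bp-del). The homozygous groups stood at 0.607 ± 0.234, 0.476 ± 0.0445 and 0.544 ± 0.139, with exact p of 0.302 to 0.675 for their differences. Replicate 5 of the 1bp-ins homozygotes, which had the highest Dhh and Amh of its group, stood at 0.971, and its 4 fellow libraries between 0.391 and 0.693.

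**Figure D4:**
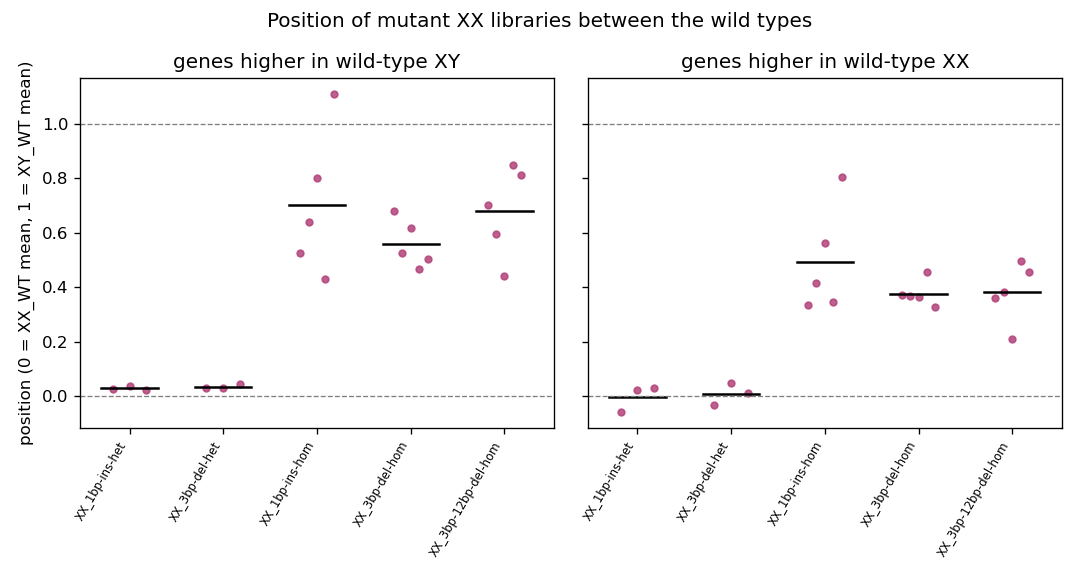
Position of mutant XX libraries between the 2 wild types, for genes higher in wild-type XY and for genes higher in wild-type XX.

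Shared calls were counted over autosomal genes tested in both comparisons. Of those called in the wild-type sex comparison, 939 (58.2%), 1063 (66.5%) and 939 (58.3%) moved towards XY in 1bp-ins, 3bp-del and 3bp-12bp-del homozygous XX gonads. Sox9, Fgf9, Foxl2 and Lefty2 were among them. Of these 418, 462 and 515 were higher in both comparisons and 521, 601 and 424 lower in both. Independent calls would give 130, 160 and 110 higher and 136, 207 and 97.7 lower. The 2 comparisons share the 3 XX wild-type libraries, which cannot be split, so part of the excess may come from shared controls. In 10 simulations with only the shared controls in common almost no gene was called in either comparison, so they set no level for the count. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.566, 0.562 and 0.567 in the simulations against 0.782, 0.722 and 0.719 in the data, and the covariance 0.057, 0.0475 and 0.0482 against 0.376, 0.314 and 0.331. With the sex difference taken from the 3bp-del heterozygotes, where no library is shared, the correlation was 0.685, 0.470 and 0.618. The share of genes that moved towards XY was then 39.1%, 41.7% and 43.0%, of a larger set of called genes. For 1bp-ins that set held 2301 higher and 1989 lower genes, against 742 and 870 with the wild types. In it 897, 918 and 1090 genes were higher in both comparisons and 781, 865 and 754 lower in both. Independent calls would give 410, 513 and 348 higher and 313, 477 and 224 lower. The shares from the 2 sets are thus not directly comparable.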

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

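The tests that weigh replicate 5 of the XX 1bp-ins homozygotes, replicate 3 of XY wild type and the XX 3bp-del heterozygotes were chosen after those results were seen.

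In replicate 5 of the XX 1bp-ins homozygotes the steroidogenic and Hedgehog programs stood far above those of its fellow libraries. The mean log2 CPM was 5.14 for the steroidogenic list and 6.03 for the Hedgehog targets. In replicate 4 of the XY 1bp-ins homozygotes the Sertoli list (6.13) and the steroidogenic list (2.57) were apart from the other 4. Replicate 4 of the XX 1bp-ins homozygotes had the lowest general germ cell mean (4.11). Replicate 4 of the XX 3bp-del homozygotes was apart in mesonephros (3.78), surface epithelium (5.13) and cholesterol synthesis genes (5.70), and replicate 1 of the XY 3bp-del homozygotes in surface epithelium (6.72), immediate early (4.37) and cholesterol synthesis genes (6.41). In replicate 2 of the XX 3bp-12bp-del homozygotes the genes near Sox9 averaged 2.50. Each was singled out by its gap to the nearest library, divided by the range of its group. Chance gives such a gap in about 1 in 20 tests, which is 5.65 of the 113 tests of a group on a measure, and 12 were found. The measures share libraries, so these tests are not independent. Only groups of 5 libraries were tested, and the groups of 3, among them both wild types and all heterozygotes, were not.

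The effect of a homozygous mutation differed between XX and XY gonads in 171 genes for 1bp-ins, 631 for 3bp-del and 97 for 3bp-12bp-del by the interaction test, with Sox9, Fgf9 and Mmd2 among them in all 3. Separately, replicate 1 of the XX 1bp-ins heterozygotes held 60 reads of Y-linked genes, where the next XX libraries held 26, 6 and 2. These are reads of genes that XX gonads lack, and no explanation for them was tested.

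Replicate 5 of the XX 1bp-ins homozygotes lay nearest to wild-type XY, at a position of 0.971 against 0.391 to 0.693 in its group. XY gonad cells would bring Y-linked RNA in proportion, and its Y-linked reads were 0.377% of the wild-type XY level. Adrenal tissue would raise the adrenal list, whose mean of -0.735 lay within the -1.911 to 1.373 of the other 4 libraries. With the gene length trend removed the position was 0.971, with the others at 0.692 or lower. These values argue against all 3 causes, no biological explanation was tested, and a difference in stage or in the extent of sex reversal between embryos stays open.

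Replicate 3 of XY wild type had the lowest Sertoli minus pregranulosa score of the XY libraries (1.63, next 2.89). XX gonad cells are argued against by Xist at 0.129% of its wild-type XX level, and a gene length trend by a score of 1.67 (next 2.90) after its removal. Mesonephros tissue in the sample may account for it in part, since its mesonephros list averaged 4.66, with -0.627 to 1.76 in the other 21 XY libraries. Its most abundant genes there were Cdh16 at 82 CPM, Wnt9b at 34.9 and Pax2 at 26.2. No biological explanation was tested, and the labels name whole gonads only.

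In XX 3bp-del heterozygotes 1721 genes were called although Sox9 was not, except without replicate 1 of XX wild type. A large shift of these gonads towards XY is argued against by their position of 0.0238. A small shift stays open, since the median Sertoli gene reached 10.7% of the wild-type switch, with the median pregranulosa gene at -2.98%. A trend with gene length between libraries may account for part of the calls, since 441 were called after its removal, 356 of them shared with the 1721. The 441 argue against that trend as the whole cause. A difference in library preparation between genotypes stays open, since the labels give no batch.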

How the results depend on the processing

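The removal of the gene length trend and the fits without libraries that stood apart were chosen after the data were seen, the other settings before. For the 359 single-gene results checked, 5289 values were computed under other settings, of which 4784 stayed on the same side of the threshold, 497 lost a call, 8 (Sox9) gained one and 0 reversed. Sox9 and Fgf9 lost no call under any setting. RLE normalization moved no count by over 1.5 times. For the settings below the cause was not tested, unless it is stated.

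With DESeq2 the counts were 2768 for XY against XX wild type, 86 and 2656 for XX 1bp-ins and 3bp-del heterozygotes, and 27, 124, 25, 179 and 135 for XY 1bp-ins heterozygotes and homozygotes, 3bp-del heterozygotes and homozygotes and 3bp-12bp-del homozygotes. They were 622 and 1769 for XX 1bp-ins and 3bp-12bp-del homozygotes against XY wild type and 260 between XX 1bp-ins and 3bp-del homozygotes. With 1 fit over all 12 groups these 11 counts were 5043, 2, 723, 1, 802, 188, 652, 210, 1960, 2290 and 49 in the same order, with 4889 for XX 3bp-del homozygotes against XY and 512, 1954 and 437 for the interactions of 1bp-ins, 3bp-del and 3bp-12bp-del. This fit shares 1 estimate of the spread among groups. With no filter the counts were 1, 3 and 1 for XY 1bp-ins heterozygotes, 3bp-del heterozygotes and 3bp-del homozygotes and 33 for XX 1bp-ins homozygotes against XY. With autosomal genes only, that last count was 3, where 10 of the 20 are autosomal.

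With the length trend removed the counts were 3439 and 441 for XX 1bp-ins homozygotes and 3bp-del heterozygotes, 5616 for XX 3bp-del homozygotes (3221 higher and 2395 lower, against 3470 and 3705, with 4384 shared with the 7175), 2 and 1 for XY 3bp-del heterozygotes and 3bp-12bp-del homozygotes, 40 for XX 1bp-ins homozygotes against XY, 2494 between 3bp-12bp-del and 3bp-del, and 148 for the 3bp-12bp-del interaction. Without the libraries that stood apart, XX 1bp-ins homozygotes against XY had 1295 and the interactions had 1978 (1bp-ins), 3834 (3bp-del) and 2959 (3bp-12bp-del).

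The replicate numbers did not pair the samples: of 58 pairs of same-numbered libraries 7 correlated above 0.1 (r from -0.319 to 0.351), and in 0 of 18 comparisons did all of them. With the numbers as a replicate block the counts were 1090 for XY against XX wild type, 507 and 1217 for XX 3bp-del heterozygotes and 3bp-12bp-del homozygotes, 0 for XY 3bp-12bp-del homozygotes (edgeR), 1, 596 and 267 for XX 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes against XY, 3 between 1bp-ins and 3bp-del, 2848 between 3bp-12bp-del and 3bp-del, and 398 and 11 for the 3bp-del and 3bp-12bp-del interactions. Under the block a library whose number has no partner adds nothing to the difference. The score differences in XX were then 4.47, 3.98 and 3.98 for 1bp-ins, 3bp-12bp-del and 3bp-del homozygotes, in designs too small to pass the threshold.

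With an axis from the 3bp-del heterozygotes the position of XX 3bp-del homozygotes was 0.408, and that of the heterozygotes was 0 by construction. With the sex difference taken from these heterozygotes, 1678, 1783 and 1844 genes moved towards XY in 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes. As a share of the genes of that sex difference these were 39.1%, 41.7% and 43.0%, against 58.2%, 66.5% and 58.3% with the wild types. In all, 162, 510 and 58 genes moved the opposite way, against 0, 25 and 5. That sex difference held more called genes (2301 higher and 1989 lower for 1bp-ins, against 742 and 870), so these shares and counts have unlike bases. With 2-fold changes in both comparisons 376, 337 and 365 moved towards XY. With an estimated correlation camera called 3 lists between the wild types, 0 in the 5 XX and the 5 XY mutant groups against their wild type, and 1, 3 and 1 in XX 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes against XY. It called 0 and 1 lists between homozygotes and heterozygotes of 1bp-ins and 3bp-del, 0 between homozygous genotypes and 1 for each interaction.

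Leaving out 1 library at a time, the counts ran from 639 to 6939 between the wild types. They ran from 0 to 1 and 165 to 1226 in XX 1bp-ins and 3bp-del heterozygotes, and from 3026 to 5604, 5620 to 8196 and 2276 to 4493 in XX 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes. In XY they ran from 0 to 5 and 0 to 0 (1bp-ins heterozygotes and homozygotes), 0 to 3 and 0 to 3 (3bp-del) and 0 to 56 (3bp-12bp-del). Against XY the XX 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes had 6 to 575, 1114 to 3555 and 323 to 2474. Homozygotes against heterozygotes had 645 to 3250 (1bp-ins) and 2653 to 5424 (3bp-del). Between genotypes there were 3 to 32 (1bp-ins against 3bp-del) and 3213 to 4810 (3bp-12bp-del against 3bp-del). The interactions had 71 to 1590, 234 to 3834 and 10 to 2959 (1bp-ins, 3bp-del, 3bp-12bp-del). Score differences ran from -0.099 to 0.413 and 0.0381 to 0.55 in XX heterozygotes and from 4.21 to 5.04, 3.57 to 4.08 and 4.25 to 4.79 in XX homozygotes. In XY they ran from 0.639 to 1.56, 0.348 to 1.27, 0.281 to 1.20, 0.212 to 1.14 and 0.245 to 1.17, in the order of the DESeq2 counts above. Without replicate 4 of the XY 1bp-ins homozygotes and replicate 1 of the XY 3bp-del homozygotes their differences (1.04 and 0.909) had an unadjusted exact permutation p under 0.05. That p was not adjusted over the XY groups, unlike the p values given with the score differences above. Positions ran from -0.004 to 0.0346 and 0.0043 to 0.0428 in heterozygotes and from 0.576 to 0.626, 0.453 to 0.493 and 0.519 to 0.561 in homozygotes.

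Other splits of the same libraries were counted with the same fit. The threshold was a share under 0.05 of splits as large as the real one, unadjusted over the comparisons. Other splits mix the groups and so raise the spread, which makes low counts likely in advance. The splits cannot tell genotype from another difference between the groups, such as batch. Only the real split was as large for XX 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes against XX wild type (5187, 7175 and 4088, highest other 0, 1 and 4 in 56 splits). The same held for 3bp-del and 3bp-12bp-del homozygotes against XY (2797 and 886, highest other 8 and 1), for homozygotes against heterozygotes (2751 and 4326, highest other 2 and 1), and between genotypes (21 and 4360, highest other 2 and 88 in 100 splits). It also held for the 1bp-ins and 3bp-del interactions (171 and 631, highest other 0 and 0 in 50 splits). Labels were exchanged there within each sex, which also removes the change in XX. For XX 1bp-ins homozygotes against XY (20) 2 of 56 splits were as large, the highest with 265, and for the 3bp-12bp-del interaction (97) 2 of 50, the highest with 932. Both shares are under 0.05, but such splits point to a structure of the samples other than genotype. Chance cannot be excluded in XY 1bp-ins and 3bp-del homozygotes (0 each, highest other 1 and 3), where all 56 splits were as large by construction, since no count lies under 0, so the splits say nothing more there. The 10 splits are too few between the wild types (1738, highest other 0), in XX 1bp-ins and 3bp-del heterozygotes (0 and 1721, highest other 3 and 1) and in XY 1bp-ins heterozygotes, 3bp-del heterozygotes and 3bp-12bp-del homozygotes (0, 0 and 2, highest other 0, 0 and 0).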

Other observations

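The tests of BC006965, of the uneven gain and loss in each library, of Hedgehog targets and of noncoding RNAs were chosen after the results were seen. The tests of mesonephros tissue and of gene choice as causes of the uneven gain and loss were written before theirs.

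Transcription next to Sox9 had different means among XY gonads, where neither Sox9 nor BC006965 was called against wild type by edgeR on the groups of each comparison. By DESeq2 and with all 12 groups in 1 fit Sox9 was called in 1bp-ins and 3bp-12bp-del homozygotes. BC006965, the divergent noncoding transcript, was at 2.21 ± 1.00 CPM in XY wild type and 8.43 ± 0.67 CPM in XY 3bp-12bp-del homozygotes (log2 fold change 1.93, adjusted p = 0.342, and 0.341 to 0.836 over the 5 XY comparisons by edgeR). It was at 6.34 ± 1.24 CPM in XY 1bp-ins homozygotes against 3.86 ± 0.31 CPM in heterozygotes, and at 6.71 ± 1.14 against 4.51 ± 0.86 CPM in 3bp-del. Each difference had an exact 2-sided permutation p = 0.0357 (n = 5 and n = 3, smallest possible 0.0179). This test repeats the difference that prompted it, so it says nothing for the candidate explanation that transcription beside Sox9 follows the number of mutant copies even where a testis forms, which stays open. The ratio of BC006965 to Sox9 was higher in homozygotes by 0.61 and 0.35 log2 units (exact p = 0.0357 each), and for Sox9 itself the exact p values were 0.625 and 0.179. The ratio rests on the same difference in the same libraries, so whether BC006965 only follows Sox9 stays open too. Reads of divergent genes may be mixed, because strand handling is not stated.

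In log2 CPM of whole gonads, homozygous XX gonads took up the genes of the XY gonad further than they gave up those of the XX gonad. In 15 of 15 libraries the position over XY-higher genes, such as Sox9 and Fgf9, lay above that over XX-higher genes, such as Foxl2 and Bmp2 (mean difference 0.230 ± 0.098, SD, exact 2-sided sign test p = 6.1e-05, the smallest that 15 libraries can give). That test repeats the pattern that prompted it. All 15 positions use the same axis from the same wild-type libraries, so the signs are not independent as the sign test assumes. In each XY mutant group, too, the mean position over XY-higher genes (1.09 to 1.16) lay above that over XX-higher genes (0.932 to 1.07). On a log2 scale a partial switch can give a larger share for genes gained from a low level than for genes lost. No linear scale was computed, so an uneven switch cannot be told from this effect of the scale. With the axis built without replicate 3 of XY wild type (1852 genes) the difference was 0.142 ± 0.077, and with the axis from the 3bp-del heterozygotes (1635 genes) 0.155 ± 0.071, positive in 15 of 15 each time. Mesonephros tissue in that replicate and the choice of genes on the wild-type libraries may account for part of the size, and these values argue against either as the whole cause. That Sertoli genes switch on before ovarian genes are silenced is a hypothesis that 1 stage cannot test.

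The Hedgehog targets, low in most homozygous XX libraries, were compared with Dhh over the 15 such libraries of 3 genotypes, the 1 relation across libraries that was computed. With both centred on the mean of their genotype, Pearson's r between the mean log2 CPM of the targets and log2 CPM of Dhh was 0.754 (permutation p = 0.0052) and Spearman's rho 0.679 (p = 0.011). Without the 2 libraries farthest from the median of centred Dhh, replicate 5 of 1bp-ins and replicate 3 of 3bp-12bp-del, r was 0.585 (p = 0.123) and rho 0.522 (p = 0.129), so the relation rests on those libraries. That the targets follow the Dhh level of the gonad may hold, and these data leave it open.

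Malat1, Kcnq1ot1, Snhg17 and Firre, 4 noncoding RNAs picked for their values, had lower means in 3bp-del heterozygotes of both sexes, with no call in XY by edgeR. Noncoding RNAs as a class were not tested. From wild type to heterozygotes Malat1 went from 247 to 50.4 CPM in XX and from 162 to 44.4 CPM in XY, Kcnq1ot1 from 36.9 to 9.05 and from 28.6 to 9.20, Snhg17 from 11.4 to 3.46 and from 9.96 to 3.31, and Firre, an X-linked RNA, from 5.27 to 2.08 and from 3.68 to 2.06. Xist went from 150 to 36.1 CPM in XX. The XY values, Firre and Xist were chosen after they were seen, and 0 genes were called in XY by edgeR (740 at unadjusted p under 0.05, 25 by DESeq2). Of the 1710 genes called in XX and measured in XY, 1399 (81.8%) moved the same way in XY, where no library is shared, against 62.8% of all 15018 genes (Pearson r across genes 0.165, which are not independent replicates). This is consistent with a shift common to the libraries of this genotype. Malat1 was at 112, 123 and 111 CPM in XX 1bp-ins, 3bp-del and 3bp-12bp-del homozygotes, lower than in XX wild type by call in the first and last only. Xist was at 51.3, 59.5 and 107 CPM, lower by call in the first 2 only. A difference between wild-type and mutant libraries in dissection, RNA quality or library batch may thus add calls to some comparisons with wild type. Batch and genotype cannot be told apart here, because the labels give no batch.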
